A study of Arabidopsis thaliana with 54 samples.

How the data were processed

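RNA from whole rosettes of Arabidopsis thaliana Col-0 was sequenced in 54 libraries, with material of 5 samples pooled in each library, per the labels. The libraries form 18 groups of 3, made of 3 conditions and 6 times (0 h and 5 later ones up to 24 h). C28P plants met 4 °C for the first time at 28 days. C35P plants, a developmental control, met it for the first time at 35 days. C28PLT plants had been primed at 28 days for 3 days at 4 °C, were returned to warm growth for a lag of 7 days, and then met cold again (triggering). Light was 200 µmol in the warm and 90 µmol in the cold, in a day of 16 h. The replicate number in the labels names an independent experiment (Exp1 to Exp3).

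The deposited table holds raw read counts per gene, which the authors made with a strand-marking library kit, Trimmomatic (version not stated), STAR 2.7.9a and DESeq2 (version not stated) on the build TAIR10, per the submitters' processing notes. The annotation version, the strand setting of the counting and the treatment of reads that fit several places are not given in the sources used here. Genes with near-identical copies are therefore uncertain as to which copy the reads came from. This holds for CBF1, CBF2 and CBF3, for KIN1 and KIN2, for COR15A and COR15B, and for the LHCB1, RBCS and PDF1.2 families, and also for overlapping and antisense genes. The table has 36632 genes and 54 columns, and 0 columns were left without a sample. All 36632 gene IDs matched a reference table of the assembly TAIR10.1, which was used for names only, so no coordinates are given. Of the 301 genes on the fixed lists, 288 symbols were found in it as symbol or synonym.

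Total counts per library ranged from 23408399 to 34452480, with a median of 28.96 M. Medians were 28.57 M in C28P (23.78 to 34.45), 29.35 M in C35P (24.91 to 31.88) and 28.01 M in C28PLT (23.41 to 30.51). Between 20466 and 23107 genes had at least 1 read. TMM factors ranged from 0.7478 to 1.207. Spearman's rho between a library's deviation from its gene means and transcript length ranged from -0.669 to 0.696, and a length and GC offset was therefore added to the alternatives. Reads are not counted by molecule, so depth gives counting error only. The spread between libraries was larger, with a common dispersion of 0.1197 (a biological coefficient of variation of 0.346). As a check for repeated libraries, the 54 pairs within groups were compared. Their log2 values correlated at 0.9269 to 0.9824, and the lowest chi-square per degree of freedom was 23.23, so no pair was a copy.

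Counts were tested with edgeR 4.0.16 under R 4.3.3. Genes were kept with filterByExpr (minimum count 10), which left 20720 genes (56.6% of the table). TMM normalization and a robust quasi-likelihood fit with 1 coefficient per group followed, on all 54 libraries with 36 residual degrees of freedom and no block. Each of 43 contrasts was tested alone, and a gene is called at a Benjamini-Hochberg adjusted p under 0.05. These are 15 contrasts of a time against 0 h, 13 between conditions at 1 time, and 15 differences of responses. An adjusted p of a gene below comes from this test unless another tool is named, SE is the standard error of the log2 fold change, and n = 3 libraries per group throughout. "Risen" and "fallen" refer to called genes.

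A total of 23 gene lists with 301 genes was tested with limma 3.58.1 (camera) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and adjustment over the lists of a contrast. The same test with an estimated correlation is the stricter alternative, and the text gives both. The root hair list was not tested because 0 of its 7 genes passed the filter (the highest count in a library was 6, or 0.201 CPM), so 22 lists were. Lists count as measured by the genes that passed the filter. The lists, the rule for named genes, the design and a set of other settings were fixed before the data were examined. By that rule the text names members of the lists. It also names, for C28P at 2 and 24 h against 0 h, for C28PLT against C35P at each time, for C35P against C28P at 0 h and for the C28PLT minus C35P differences of responses, up to 10 called genes per direction with the largest change. These need a mean of at least 5 CPM in a group and the same sign in each of the 3 experiments. Its last part, genes called between C28PLT and C35P at most times, named 0 genes. Of the called genes, those still called when any 1 library was left out were preferred as examples, a choice made after their values were seen.

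The size of the cold response was compared between C28PLT and C35P on genes called in C28P with an absolute log2 fold change of at least 1. Their mean change per experiment was taken with the sign turned for fallen genes, so that a larger fall counts higher. It was set side by side with a two-sided exact permutation test of 3 against 3 values, whose smallest possible p is 0.1. Other permutation tests used 1e+05 draws.

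On simulated counts with 200 changed genes among 20720, the test of C28P at 24 h against 0 h recovered 26% of 2-fold, 62% of 4-fold, 82% of 8-fold and 90% of 16-fold changes, with 7 false calls. For C28PLT against C35P at 0 h these were 10%, 64%, 88% and 90%, with 6 false calls. For the C28PLT minus C35P difference of responses at 2 h they were 6%, 48%, 78% and 82%, with 6 false calls. With 200 changed genes, a doubling was therefore mostly missed at this spread. The real contrast of C28P at 24 h called 6038 genes, of which 2032 rose and 2290 fell by at least 2-fold. Smaller changes were thus called there too, and the simulated shares do not carry over to contrasts with many called genes.

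The replicate number marks an independent experiment in the labels. It is taken to pair libraries within a condition and across conditions, though the labels do not say that conditions of 1 number were grown side by side. Deviations from group means were checked between libraries of the same experiment and time. Between C28P and C35P their mean correlations were 0.391, 0.327 and 0.153 in Exp1, Exp2 and Exp3. Between C28PLT and C35P they were -0.11, -0.156 and 0.257, and between C28PLT and C28P 0.0233, -0.184 and 0.0495. For C28PLT these do not show a pairing with the other conditions, so differences per experiment that involve it rest on the shared number alone. Within a condition, the mean correlation among libraries of 1 experiment was 0.0658 to 0.459, and single libraries correlated with the 0 h library of their experiment at -0.353 to 0.604.

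Other settings fixed in advance were DESeq2 1.42.0, RLE factors, no filter on low counts, the replicate block, a fit of only the groups compared, an estimated correlation for the lists, other summaries of the response size, and leaving out each library or experiment in turn. A total of 8 alternatives was added after seeing the data. They use a per-library length and GC offset (splines with 5 degrees of freedom each, on genes with a mean log2 CPM of at least 1), the 9 condition-by-experiment sets as blocks, combinations of these, a fit without the C28P 0 h library of Exp1, and leaving out each library for each named gene. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Alignment was not repeated, and reads were not analysed here.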

Results

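Gene expression in whole rosettes was followed through a first and a second exposure to 4 °C. Each of 18 groups holds 3 libraries, 1 from each of 3 independent experiments, so each condition has 18 libraries. C28P is the first cold of 28-day plants and C35P the first cold of 35-day plants that serve as the developmental control. C28PLT is the second cold of plants that had been through 3 cold days and a lag of 7 warm days. The values are read counts per gene, given as CPM (counts scaled to library size by TMM) or as log2 fold changes. Totals per library ran from 23408399 to 34452480 counts, and 20720 genes were tested. Only 24 h shares its time of day with 0 h, and no warm control stands beside 2 to 12 h, so the earlier changes hold time of day as well as cold. Light also dropped from 200 µmol in the warm to 90 µmol in the cold, so every change from 0 h, that at 24 h included, holds the dimmer light too.

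The first question is what changes after the move to cold and dimmer light in 28-day plants that had not met cold before. At 2 h, RVE2 (AT5G37260), a MYB-like factor of the clock family, rose 11.7-fold, from 5.09 to 59.2 CPM (log2 3.54, SE 0.613, adjusted p = 0.00158 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3). SPX1 (AT5G20150), a sensor of phosphate status, rose 10.9-fold (SE 0.599), the B-box factor BBX29 (AT5G54470) rose 7.61-fold (SE 0.407) and the kinase gene MAPKKK13 (AT1G07150) rose 6.09-fold (SE 0.47). The heat-shock factor AT-HSFB2B (AT4G11660) fell 8.19-fold (SE 0.412, edgeR adjusted p = 9.05e-05), and the ethylene-type factor ESE3 (AT5G25190) fell 6.05-fold (SE 0.444). CBF3 (AT4G25480), which switches on genes of cold tolerance, rose 9.60-fold (SE 0.793, edgeR adjusted p = 0.0482). At 0 h it stood at 71.6 CPM in Exp1 against 1.02 and 4.14, and without that library it rose 96.8-fold (SE 0.854, edgeR adjusted p = 4.26e-06), while SPX1 rose 19.3-fold. Its call was lost without any of 5 of the 6 libraries, namely the 2 h libraries of all 3 experiments and the 0 h libraries of Exp2 and Exp3, with an adjusted p of at most 0.453 (edgeR, without the 0 h library of Exp3). A total of 81 genes was called, 38 risen and 43 fallen, a count that depends on the model: it was 155 with the replicate block, 398 with a block per condition and experiment, 606 with that block and the length and GC offset, 238 with DESeq2 and 0 in a fit of only the groups compared. The 0 h library of Exp1 stood apart, with PRR5 at 77.2 CPM against 0.949 and 1.14 in the other experiments, and 631 genes were called without it. The count was 39 without the 0 h library of Exp2, 19 without that of Exp3, and 29 and 39 without the 2 h libraries of Exp2 and Exp3.

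Among the gene lists at 2 h in C28P, the CBF/DREB1 factors stood out with a median log2 change of 3.24 (limma's camera, adjusted p = 0.000161, but adjusted p = 0.479 with an estimated correlation). Of these 6 genes, 1 rose over all genes and 3 adjusted over the list alone. Clock genes had a median of 0.60 (camera adjusted p = 0.000161, and adjusted p = 0.479 with an estimated correlation), with 0 of 19 called by edgeR. COR and LEA genes, which encode protective proteins of the cold response, had 0 of 19 called and a median of 0.16 (camera adjusted p = 0.08). Their mean change was -0.87, 1.70 and 0.61 in Exp1, Exp2 and Exp3, and that of the clock genes -0.41, 1.51 and 1.80. Without the 0 h library of Exp1, 3 COR and LEA genes rose (median 1.60, camera adjusted p = 0.00315, and adjusted p = 0.595 with an estimated correlation) and 7 clock genes did (median 1.48, camera adjusted p = 1.27e-07, and adjusted p = 0.128 with an estimated correlation). The early cold-induced factors had 0 risen and 1 fallen of 16, against 3 and 2 adjusted over the list alone (camera adjusted p = 0.45), and 3 risen and 1 fallen without the 0 h library of Exp1. Smaller shifts were called by camera in 4 more lists, and 0 of them was called with an estimated correlation. They were the jasmonate genes (median 1.01, adjusted p = 0.0409, and 0.863 with an estimated correlation), the regulators upstream of CBF (0.46, 0.0409 and 0.6), the abscisic acid genes (0.22, 0.0392 and 0.6) and light harvesting (-0.18, 0.0392 and 0.863). Each of these 4 calls was lost when an experiment was left out, with adjusted p of 0.155 and 0.0606 without Exp1 and Exp3 (jasmonate), 0.0577 and 0.848 without Exp2 and Exp3 (regulators), 0.0726 and 0.149 without Exp1 and Exp2 (abscisic acid), and 0.0812 and 0.934 without Exp1 and Exp3 (light harvesting). Without the 0 h library of Exp1 alone, the adjusted p was 0.339 (jasmonate), 0.0314 (regulators), 0.0736 (abscisic acid) and 0.0713 (light harvesting). With the replicate block the regulators had an adjusted p of 0.0503.

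At 24 h in C28P the changes were larger. KIN1 (AT5G15960), a small cold-induced hydrophilic protein, rose 47.1-fold, from 15.4 to 727 CPM (log2 5.56, SE 0.661, edgeR adjusted p = 6.33e-08, n = 3). LTI30 (AT3G50970), a dehydrin, rose 39.8-fold (SE 0.852), and ELIP1 (AT3G22840), which binds chlorophyll under light stress, rose 34.3-fold to 3191 CPM (SE 0.539). EXPA8 (AT2G40610), an expansin that loosens cell walls, fell 73.2-fold (SE 0.732, edgeR adjusted p = 6.05e-08) and the gibberellin-regulated GASA6 (AT1G74670) fell 68.3-fold (SE 0.669). PIF4 (AT2G43010), which drives growth in warmth, fell 15.5-fold (SE 0.294, edgeR adjusted p = 1.97e-12). These calls held without any 1 of the 6 libraries, and without the 0 h library of Exp1 LTI30 rose 123-fold and ELIP1 62.2-fold. Among 6038 called genes, 2873 rose and 3165 fell.

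By list at 24 h in C28P, 14 of 19 COR and LEA genes rose, COR15A 22.6-fold and RD29A 11.7-fold among them (median log2 3.14, camera adjusted p = 1.78e-09, and adjusted p = 0.248 with an estimated correlation). Genes of flavonoid and anthocyanin synthesis rose in 12 of 17 cases (14 adjusted over the list alone), with TT4, the entry enzyme, up 6.02-fold (median 2.11, camera adjusted p = 3.2e-08, and adjusted p = 0.248 with an estimated correlation). Light harvesting and Rubisco genes fell in 19 of 21 cases (20 adjusted over the list alone), LHCB4.2 by 6.57-fold (median -1.25, camera adjusted p = 9.07e-15, and adjusted p = 0.152 with an estimated correlation). Of the genes for ribosome assembly and RNA chaperones, 10 of 13 rose, such as FIB2 6.51-fold and GRP7 11.4-fold (median 1.34, camera adjusted p = 1.1e-05, and adjusted p = 0.237 with an estimated correlation). In proline and sugar metabolism 8 of 16 rose and 2 fell, with SUS1 up 12.7-fold and BAM3 up 7.65-fold (median 1.23, camera adjusted p = 0.00758, and adjusted p = 0.429 with an estimated correlation). Touch and calcium genes fell in 4 of 7 cases, XTH22 by 41.4-fold (median -1.96, camera adjusted p = 0.00758, and adjusted p = 0.383 with an estimated correlation). Jasmonate genes fell in 3 of 17 cases (median -1.20, camera adjusted p = 0.0439, and adjusted p = 0.886 with an estimated correlation), and that camera call was lost without Exp1 (adjusted p = 0.0782). The 0 h library of Exp1 lowers several of these folds by over 1.5 times, and without it RD29A rose 58.8-fold, GRP7 48.6-fold, SUS1 19.7-fold and BAM3 18.7-fold.

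The remaining lists at 24 h in C28P were not called by camera, but several members were. In photoprotection 4 of 8 rose (median 0.48, camera adjusted p = 0.0606), and without the 0 h library of Exp1 3 rose and 1 fell (camera adjusted p = 0.0454, and adjusted p = 0.281 with an estimated correlation). Of the early cold-induced factors 1 rose and 5 fell of 16 (median -1.08), ERF104 by 42.2-fold. The clock had 4 risen and 3 fallen of 19 (median 0.14), with TOC1 up 3.26-fold and CHE down 6.62-fold. The mean change of the clock list was -0.69, 1.48 and 1.08 in Exp1, Exp2 and Exp3. Without the 0 h library of Exp1, where TOC1 stood at 28.1 CPM against 4.92 and 3.14, TOC1 rose 9.72-fold and 9 clock genes rose and 2 fell (median 1.08, camera adjusted p = 0.0226, and adjusted p = 0.506 with an estimated correlation). Membrane lipid genes split into 2 risen and 3 fallen of 9 (median 0.016), with DGAT1 up 3.94-fold (14.7-fold without that library) and FAD2 down 1.78-fold. In abscisic acid signalling 3 rose and 1 fell of 11 (median 0.58), and NCED3, which makes the hormone, rose 8.64-fold. Without the 0 h library of Exp1, 5 abscisic acid genes rose and 1 fell, membrane lipid genes had 3 risen and 2 fallen, and heat-shock genes 2 fallen, gibberellin genes 1 risen and 3 fallen, and the regulators upstream of CBF 3 risen and 1 fallen. Redox genes had 2 risen and 3 fallen of 15 (median -0.18), salicylate genes 1 and 2 of 16 (-0.32), gibberellin genes 0 and 3 of 8 (-0.28) and flowering genes 3 and 3 of 19 (-0.29). The regulators upstream of CBF had 2 risen and 1 fallen of 19 (median 0.15, mean -0.13), and heat-shock genes 0 and 1 of 10 (-1.09). Senescence had 1 risen of 8 (-0.067) and the reference genes 1 of 10 (-0.13). The CBF/DREB1 factors (median 0.27, mean -0.13) and the floral organ markers (-0.48) had 0 of 6 called by edgeR. The former changed by a mean of -1.49, 1.94 and 0.16 in Exp1, Exp2 and Exp3, and without the 0 h library of Exp1 CBF3 rose 10.8-fold (edgeR adjusted p = 0.000423) and the median of the list was 1.51 (camera adjusted p = 0.631).

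The numbers of called genes grew with time in each condition up to 12 h. In C28P they were 1640 at 4 h, 3747 at 6 h and 4397 at 12 h. Without the 0 h library of Exp1 these were 2377, 5347 and 5096. Without that of Exp2 they were 828, 2273 and 2912, and without that of Exp3 they were 662 at 4 h and 1943 at 6 h. Leaving out the 4 h libraries of Exp1 or Exp2 left 954 or 1003 genes at 4 h, and leaving out the 6 h libraries of Exp1 or Exp3 left 2385 or 2375 at 6 h. In C35P the numbers were 407, 2125, 3625, 5200 and 5958 from 2 to 24 h. They fell to 194, 260 and 218 at 2 h without the 0 h library of Exp3 or the 2 h libraries of Exp1 and Exp2, and to 1398 at 4 h without the 4 h library of Exp2. In C28PLT they were 575, 2638, 3712, 5509 and 5364. Without a 0 h library they were 363, 376 and 299 at 2 h (Exp1, Exp2 and Exp3), without the 2 h library of Exp1 or Exp2 363 and 328, and without the 4 h library of Exp1 or Exp2 1719 and 1731 at 4 h.

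**Figure D1:**
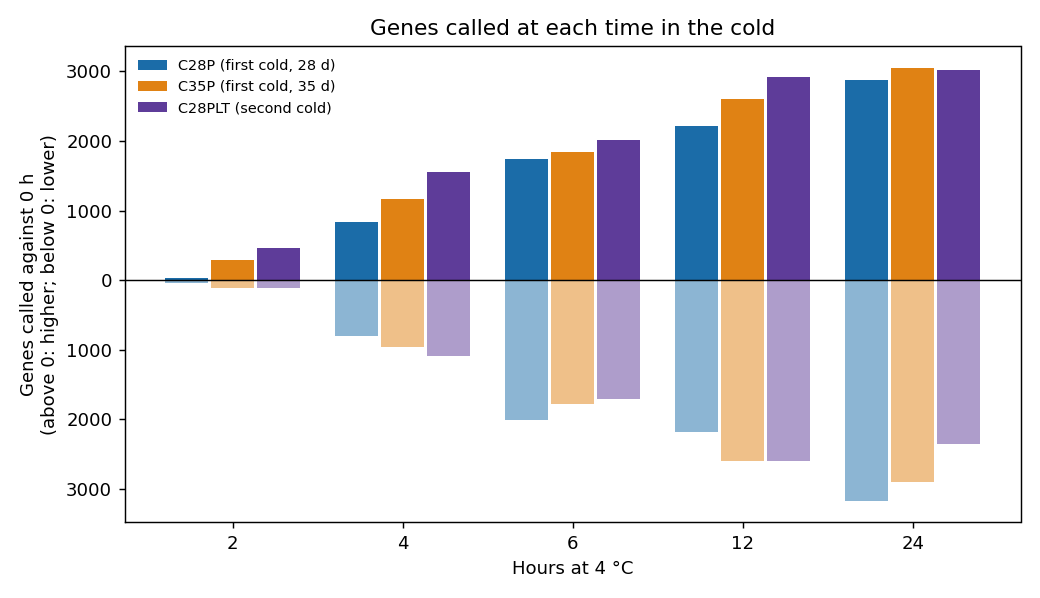
Number of genes called higher or lower than at 0 h (bars, edgeR, adjusted p under 0.05) at 2, 4, 6, 12 and 24 h in C28P, C35P and C28PLT. The counts run from 81 genes in C28P at 2 h to 6038 in C28P at 24 h.

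The same comparison in 35-day plants asks what changes in a first cold at the later age. At 2 h CBF3 rose 136-fold (log2 7.09, SE 0.954, edgeR adjusted p = 2.35e-05, n = 3). RAV1 (AT1G13260), an early cold-induced factor, rose 6.69-fold (SE 0.449), and CRF3 (AT5G53290), a cytokinin response factor, rose 11.5-fold (SE 0.514). The clock genes PRR5 (AT5G24470), FKF1 (AT1G68050) and LUX (AT3G46640) rose 71.5-fold (SE 0.932), 59.8-fold (SE 0.907) and 6.26-fold (SE 0.392), and 2 h is also later in the day than 0 h. ADS2 (AT2G31360), a desaturase of membrane lipids, rose 7.88-fold (SE 0.478), and GA2OX1 (AT1G78440), which inactivates gibberellin, rose 6.84-fold (SE 0.582). These calls held without any 1 of the 6 libraries. CBF1 and CBF2 rose 24.2-fold and 18.4-fold, and both calls were lost without the 0 h library of Exp1 or Exp3 or the 2 h library of Exp3 (edgeR adjusted p of at most 0.18 and 0.137). A total of 295 genes rose and 112 fell.

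By list at 2 h in C35P, 3 of the 6 CBF/DREB1 factors rose (5 adjusted over the list alone), with a median of 3.83 (camera adjusted p = 1.3e-09, and adjusted p = 0.0262 with an estimated correlation). Of 19 clock genes 4 rose (9 adjusted over the list alone; median 0.91, camera adjusted p = 3.84e-11, and adjusted p = 0.0262 with an estimated correlation). Among COR and LEA genes 9 of 19 rose (11 adjusted over the list alone; median 1.62, camera adjusted p = 3.42e-10, and adjusted p = 0.277 with an estimated correlation). Early cold-induced factors had 3 risen and 1 fallen of 16 (4 and 2 adjusted over the list alone; median 0.51, camera adjusted p = 0.00029, and adjusted p = 0.502 with an estimated correlation). That camera call was lost without Exp3 (adjusted p = 0.628). Another 5 lists were called by camera, with adjusted p from 0.0108 to 0.0174, and 0 of them with an estimated correlation. These were proline and sugar metabolism (median 0.56), jasmonate (0.74), abscisic acid (0.15), ribosome assembly (0.30) and light harvesting (-0.19). Calls were lost without Exp3 for proline and sugar (adjusted p = 0.0662) and jasmonate (0.0918), without Exp2 for ribosome assembly (0.0549) and without Exp1 for light harvesting (0.0708).

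At 24 h in C35P, GOLS3 (AT1G09350), which makes galactinol for raffinose, rose 114-fold (log2 6.84, SE 0.908, edgeR adjusted p = 3.56e-07, n = 3) and COR15A (AT2G42540), which guards chloroplast membranes, rose 45.1-fold (SE 0.562). GRP7 (AT2G21660), an RNA chaperone of the cold and the clock, rose 49.3-fold (SE 0.614), and SUS1 (AT5G20830), a sucrose synthase, rose 25.3-fold (SE 0.46). XTH22 (AT5G57560), a cell-wall enzyme that responds to touch, fell 63.3-fold (SE 1, edgeR adjusted p = 1.59e-05). LHCB4.2 (AT3G08940), a light-harvesting antenna protein, fell 6.66-fold (SE 0.275) and PIF4 fell 12.8-fold (SE 0.29). Of 5958 called genes 3055 rose and 2903 fell. COR and LEA genes rose in 16 of 19 cases (median 4.2, camera adjusted p = 6.36e-15, and adjusted p = 0.0857 with an estimated correlation). Light harvesting fell in 18 of 21 cases (19 adjusted over the list alone; median -1.21, camera adjusted p = 5.18e-14, and adjusted p = 0.0857 with an estimated correlation). Flavonoid genes rose in 10 of 17 cases (11 adjusted over the list alone; median 2.09, camera adjusted p = 7.86e-07, and adjusted p = 0.312 with an estimated correlation), and ribosome assembly in 10 of 13 (median 1.52, camera adjusted p = 2.02e-07, and adjusted p = 0.0857 with an estimated correlation). Proline and sugar genes had 8 risen and 2 fallen of 16 (median 1.12, camera adjusted p = 0.00465, and adjusted p = 0.358 with an estimated correlation). Touch genes fell in 4 of 7 cases (median -1.81, camera adjusted p = 0.00909, and adjusted p = 0.358 with an estimated correlation), and this camera call was lost without Exp1 (adjusted p = 0.107).

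Lists not called by camera at 24 h in C35P again held called members. The clock had 9 risen and 3 fallen of 19 (median 1.08, camera adjusted p = 0.0715), with TOC1 up 9.53-fold. Photoprotection had 4 risen and 1 fallen of 8 (median 0.45), with ELIP1 up 57.6-fold. Heat-shock genes fell in 5 of 10 cases (median -1.65), HSFA2 by 14.7-fold. Membrane lipid genes had 3 risen and 3 fallen of 9 (median -0.18, mean 0.62), with ADS2 up 7.94-fold and DGAT1 up 14.9-fold. Of the CBF/DREB1 factors only CBF3 was called, 8.92-fold up (median 1.19). The early factors had 1 risen and 4 fallen of 16 (median -0.52), jasmonate 0 and 4 of 17 (-0.87), abscisic acid 3 and 1 of 11 (0.17) and redox 2 and 2 of 15 (-0.24). Salicylate genes had 1 risen and 1 fallen of 16 (-0.49), gibberellin genes 0 and 2 of 8 (-0.61), and flowering genes 4 and 3 of 19 (0.075). The regulators upstream of CBF had 3 and 1 of 19 (-0.083), senescence 1 risen of 8 (0.42), reference genes 1 of 10 (0.024) and the floral organ markers 0 of 6 (-0.91).

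The second cold asks how primed plants respond when they meet 4 °C again. At 2 h in C28PLT, CBF1 (AT4G25490), CBF2 (AT4G25470) and CBF3 rose 69.6-fold (log2 6.12, SE 1.27), 66.2-fold (SE 1.11) and 160-fold (SE 0.964, edgeR adjusted p = 8.41e-06, n = 3). RAV1 rose 13-fold (SE 0.469, edgeR adjusted p = 6.3e-06), CRF2 (AT4G23750) 5.58-fold (SE 0.394), MYB73 (AT4G37260) 6.19-fold (SE 0.52) and the zinc-finger gene CZF1 (AT2G40140) 4.12-fold (SE 0.395). PRR5 rose 121-fold (SE 0.981), ADS2 8.20-fold (SE 0.479), and XTH22 19-fold (SE 0.921, edgeR adjusted p = 0.004). HSFA2 (AT2G26150), a heat-shock factor, fell 15.6-fold (SE 0.781). These calls held without any 1 of the 6 libraries. A total of 460 genes rose and 115 fell. With the length and GC offset the split was 497 and 224 at 2 h, and at 4 h it went from 1557 and 1081 to 1501 and 1736. The offset is fitted to each library's deviation from the gene means over all libraries. It can therefore recentre a library, or take out a cold response that goes with length or GC. At 6 h it moved the median gene to -0.105.

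By list at 2 h in C28PLT, 4 of the 6 CBF/DREB1 factors rose (6 adjusted over the list alone), with a median of 6.09 (camera adjusted p = 2.26e-13, and adjusted p = 0.0084 with an estimated correlation). Early cold-induced factors rose in 7 of 16 cases (12 adjusted over the list alone; median 2.35, camera adjusted p = 3.73e-20, and adjusted p = 0.0126 with an estimated correlation). Among COR and LEA genes 2 of 19 rose (8 adjusted over the list alone; median 1.33, camera adjusted p = 8.48e-08, and adjusted p = 0.264 with an estimated correlation), ERD4 3.41-fold among them. Of 19 clock genes 3 rose (6 adjusted over the list alone; median 1.02, camera adjusted p = 2.14e-07, and adjusted p = 0.0865 with an estimated correlation). Touch genes rose in 3 of 7 cases (4 adjusted over the list alone; median 1.73, camera adjusted p = 0.000674, and adjusted p = 0.248 with an estimated correlation). Salicylate genes rose in 2 of 16 (4 adjusted over the list alone; median 1.02, camera adjusted p = 6.48e-07) and jasmonate genes in 0 of 17 (5 adjusted over the list alone; median 1.3, camera adjusted p = 2.64e-06), both with adjusted p = 0.278 with an estimated correlation. Heat-shock genes had 1 fallen of 10 (median -1.16, camera adjusted p = 0.00526, and adjusted p = 0.294 with an estimated correlation). Abscisic acid genes had 4 risen of 11, such as CYP707A1, which breaks the hormone down, 7.28-fold. Their median was -0.056, their mean 0.83, and camera called them up (adjusted p = 0.0123, and adjusted p = 0.278 with an estimated correlation). That camera call was lost without Exp3 (adjusted p = 0.253).

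**Figure D2:**
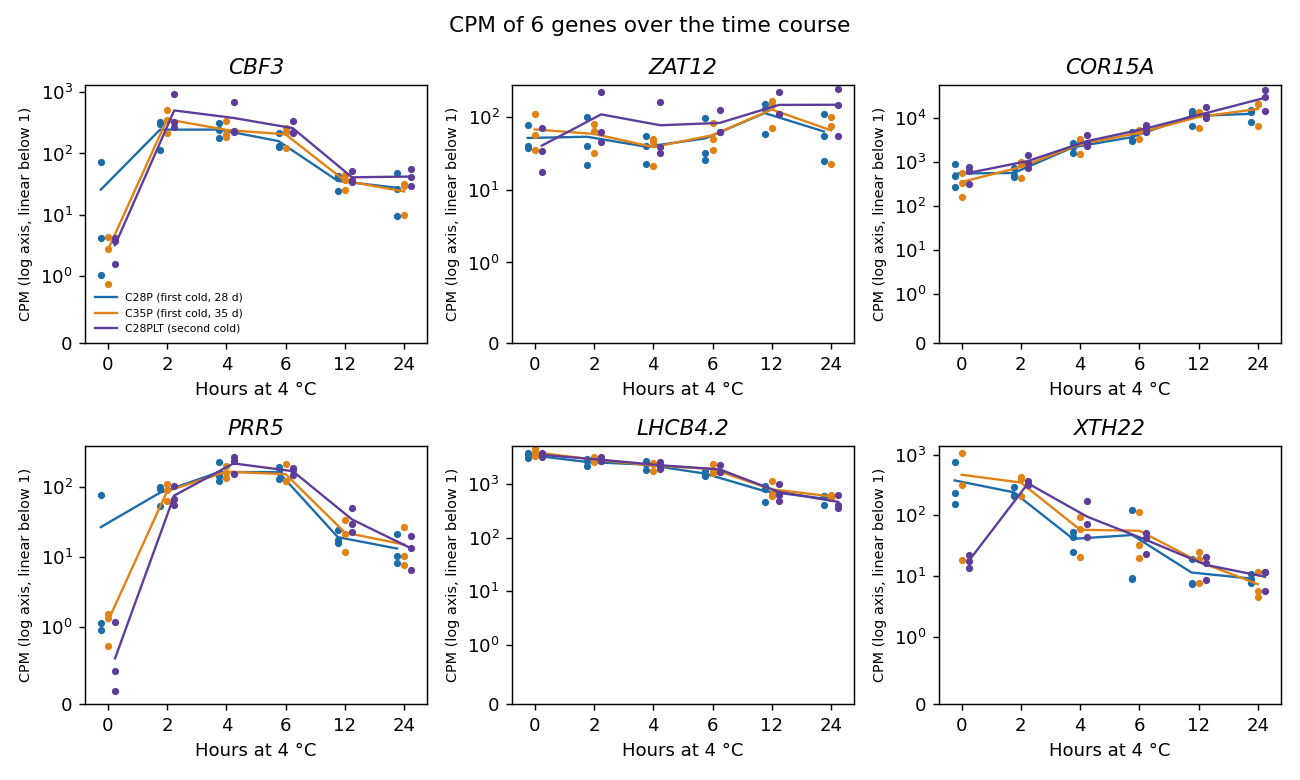
CPM of CBF3, ZAT12, COR15A, PRR5, LHCB4.2 and XTH22 at 0 to 24 h of cold (log axis, linear below 1), with 1 point per library and lines through the means of C28P, C35P and C28PLT. PRR5 and CBF3 at 0 h show the C28P library of Exp1 far above the other 2 experiments (77.2 against 0.949 and 1.14 CPM for PRR5).

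At 24 h in C28PLT, COR15A rose 50.2-fold (log2 5.65, SE 0.566, edgeR adjusted p = 1.31e-09, n = 3), KIN1 70.4-fold (SE 0.678), LTI30 119-fold (SE 0.917), and GOLS3 80.9-fold (SE 0.887). CRF3 stayed up 13.5-fold and CBF3 13.3-fold (SE 0.824). OXI1 (AT3G25250), a kinase of oxidative signalling, rose 8.67-fold, and the jasmonate enzyme gene AOC2 (AT3G25770) rose 5.34-fold. PIF4 fell 15.6-fold (SE 0.295, edgeR adjusted p = 8.61e-13) and LHCB4.2 fell 7.53-fold (SE 0.277). Of 5364 called genes 3019 rose and 2345 fell, and with the length and GC offset 3353 rose and 3541 fell. COR and LEA genes rose in 16 of 19 cases (18 adjusted over the list alone; median 4.15, camera adjusted p = 2.28e-17, and adjusted p = 0.0757 with an estimated correlation). Light harvesting fell in 16 of 21 cases (18 adjusted over the list alone; median -1.14, camera adjusted p = 1.69e-13, and adjusted p = 0.0757 with an estimated correlation). Flavonoid genes rose in 13 of 17 cases (14 adjusted over the list alone; median 2.26, camera adjusted p = 5.88e-09, and adjusted p = 0.16 with an estimated correlation), with the regulator PAP2 up 14.5-fold. Ribosome assembly rose in 10 of 13 cases (median 1.37, camera adjusted p = 2.4e-07, and adjusted p = 0.0757 with an estimated correlation). Proline and sugar genes had 6 risen and 1 fallen of 16 (7 and 2 adjusted over the list alone; median 0.94, camera adjusted p = 0.029, and adjusted p = 0.522 with an estimated correlation). CBF/DREB1 factors had 3 risen of 6 (median 3.10, camera adjusted p = 0.0422, and adjusted p = 0.522 with an estimated correlation), and photoprotection 3 of 8 (median 0.56, camera adjusted p = 0.0215, and adjusted p = 0.147 with an estimated correlation). These last 3 camera calls were lost without Exp3 (adjusted p = 0.0625, 0.139 and 0.0557), and that of proline and sugar also without Exp2 (0.14).

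Among the other lists at 24 h in C28PLT, the early factors had 5 risen and 2 fallen of 16 (median 0.88, camera adjusted p = 0.134), with ZAT6 up 10.1-fold and ERF105 down 7.08-fold. Abscisic acid genes had 5 risen and 1 fallen of 11 (median 0.63), with NCED3 up 10.6-fold. Redox genes had 5 risen and 0 fallen of 15 (0.25), the clock 8 and 4 of 19 (0.68), and membrane lipid genes 3 and 2 of 9 (median -0.13, mean 0.60). Heat-shock genes had 2 fallen of 10 (6 adjusted over the list alone; median -2.12), touch genes 1 fallen of 7 (-0.25), jasmonate 1 risen and 1 fallen of 17 (0.44) and salicylate 1 and 3 of 16 (0.12). Gibberellin genes had 3 risen and 2 fallen of 8 (0.67), flowering genes 2 and 3 of 19 (0.22), and the regulators upstream of CBF 2 and 1 of 19 (-0.15). Senescence had 1 risen of 8 (0.20), the reference genes 1 risen and 1 fallen of 10 (-0.21), and the floral organ markers 0 of 6 called (-0.47).

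**Figure D3:**
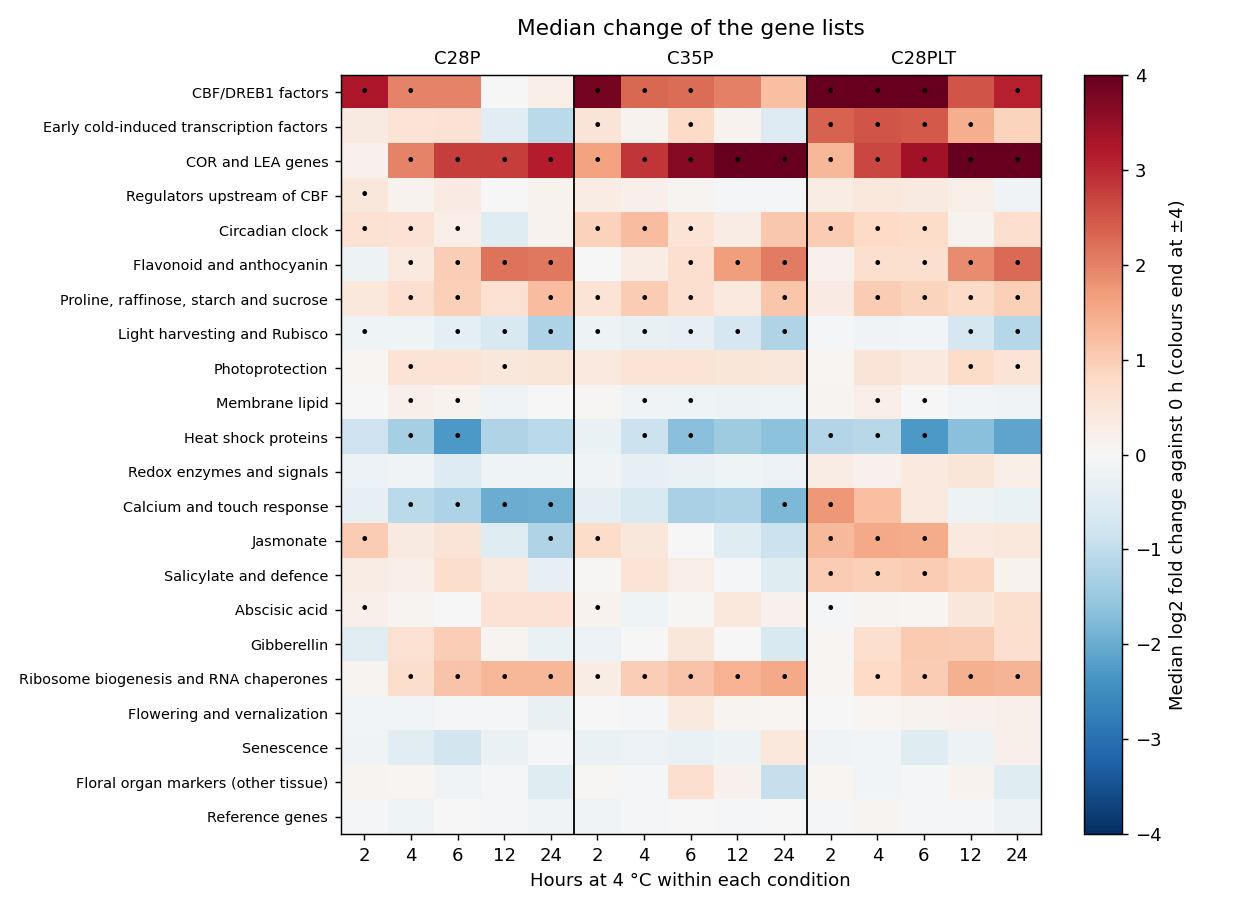
Median log2 fold change against 0 h of 22 gene lists (lines of the map) at 2 to 24 h in C28P, C35P and C28PLT, as colour, with a dot where camera called the list at the preset correlation. The COR and LEA genes reach medians of 3.14, 4.2 and 4.15 at 24 h, and light harvesting -1.25, -1.21 and -1.14.

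Called genes overlapped between conditions, which have no library in common, by more than independent lists would. At 24 h, C28PLT and C35P shared 2131 risen genes, where independent lists of those sizes would share 445, and 1750 fallen genes (chance 329). C28P and C35P shared 2214 risen (chance 424) and 2265 fallen (chance 443), and C28PLT and C28P shared 1862 (chance 419) and 1664 (chance 358). At 2 h, C28PLT and C35P shared 219 risen genes (chance 6.55) and 59 fallen ones (chance 0.622). Between 0 and 3 genes were called in opposite directions in any of these pairs. Called in all 3 conditions were 34 risen and 23 fallen genes at 2 h, of 712 called in 1 or more, and 1690 risen and 1516 fallen ones at 24 h, of 8676. Log2 changes correlated across genes at 0.406 to 0.6 at 2 h and at 0.707 to 0.846 at 24 h, where genes are not independent replicates.

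The central question is whether plants that had been cold before differ from plants of the control at the same time. C28PLT and C35P were not matched in calendar age. Age at first cold, priming and lag together made C28PLT plants older in days at 0 h than C35P plants. Each comparison of C28PLT with C35P, differences of responses included, therefore holds some age as well as priming. At 0 h, XTR6 (AT4G25810), a cell-wall enzyme of the touch-responsive xyloglucan family, was 19.4-fold lower in C28PLT, at 1.28 against 24.7 CPM (log2 -4.27, SE 0.758, edgeR adjusted p = 0.0289, n = 3). It was the only gene called of 20720. With the replicate block its edgeR adjusted p was 0.0681. The call was also lost without any 1 of the C28PLT libraries or without the C35P library of Exp1 (edgeR adjusted p of at most 1, with a log2 change of -1.69 there). Without the C35P libraries of Exp2 or Exp3 19 or 93 genes were called, without the C28PLT library of Exp1 2 genes, and in each other case 0. Its relative XTH22 had a log2 difference of -4.72 (SE 0.942, edgeR adjusted p = 0.0557), and ERF104, a factor induced within minutes of stress, stood at -2.68 (SE 0.62, edgeR adjusted p = 0.0977), so neither was called. COR15A and KIN1 had differences of 0.68 (SE 0.465) and 1.06 (SE 0.553) and were not called (both with an edgeR adjusted p of 1).

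By list at 0 h, the early cold-induced factors were lower in C28PLT than in C35P (median -1.3, 14 of 16 below 0, camera adjusted p = 5.09e-09, and adjusted p = 0.179 with an estimated correlation). Of them 0 were called over all genes and 8 adjusted over the list alone. Touch genes were lower too (median -1.41, 7 of 7 below 0, camera adjusted p = 2.22e-05, and adjusted p = 0.168 with an estimated correlation), with 2 called adjusted over the list alone. Redox genes had a median of -0.32 (camera adjusted p = 0.00414, and adjusted p = 0.0558 with an estimated correlation). Without Exp2 these 3 camera calls were lost, with adjusted p of 0.119, 0.0883 and 0.119. COR and LEA genes were higher by a median of 0.53 and in each of the 3 experiments (camera adjusted p = 0.00122, and adjusted p = 0.818 with an estimated correlation), and that call too was lost without Exp2 (0.0883). Jasmonate genes (-0.84, camera adjusted p = 0.00779), light harvesting (-0.17, 0.0126) and senescence genes (0.58, 0.0434) had adjusted p of 0.818, 0.818 and 0.687 with an estimated correlation. They lost the camera call without Exp2 (jasmonate, 0.66), without Exp1 (light harvesting, 0.481) and without Exp1 or Exp2 (senescence, 0.229 and 0.119).

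During the cold itself, edgeR called 0 genes between C28PLT and C35P at 2, 4, 6, 12 and 24 h. At an unadjusted p under 0.05 there were 176, 184, 114, 206 and 669 genes, and DESeq2 called 0 at each of these times (48 at 0 h, where 752 had an unadjusted p under 0.05). At 6 h 1 gene was called without the C28PLT library of Exp1 or of Exp3. CBF1, CBF2 and CBF3 at 2 h were 1.66 (SE 1.03), 1.07 (SE 0.903) and 0.48 (SE 0.726) higher on the log2 scale in C28PLT, each with an edgeR adjusted p of 1. At 24 h COR15A stood 0.84 (SE 0.466) and KIN1 1.23 (SE 0.55) higher, both with an edgeR adjusted p of 0.818. Camera called 5, 0, 6, 7 and 3 lists from 2 to 24 h, and 0 of these with an estimated correlation. Those at 2, 6 and 12 h were lost without Exp1. At 24 h the called lists were COR and LEA genes (median 0.59, camera adjusted p = 0.000208), jasmonate genes (0.68, 0.00104) and abscisic acid genes (0.39, 0.0379), each with an adjusted p of 0.733 with an estimated correlation. Of these, jasmonate was lost without Exp1 (0.257) and abscisic acid without Exp2 (0.347). In COR and LEA genes the mean difference at 24 h was 1.61, -0.14 and 0.60 in Exp1, Exp2 and Exp3.

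**Figure D4:**
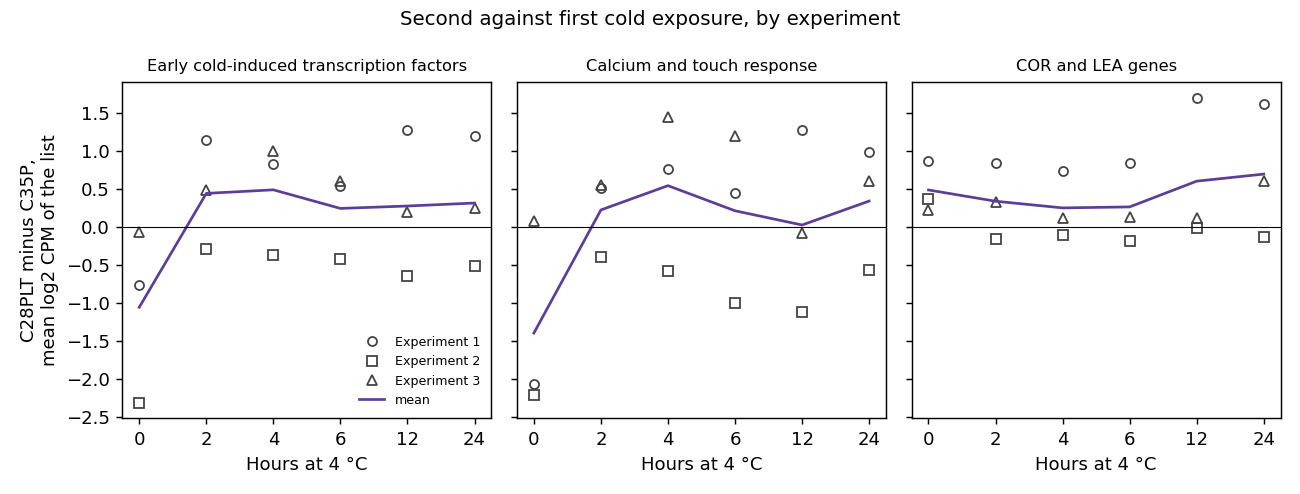
Mean log2 CPM of C28PLT minus that of C35P for 3 gene lists at 0 to 24 h, with 1 point per experiment and a line through the mean. For the early cold-induced factors the points are -0.77, -2.32 and -0.073 at 0 h and 1.14, -0.30 and 0.48 at 2 h, and for the COR and LEA genes 1.61, -0.14 and 0.60 at 24 h.

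Whether the cold response itself differed between the second and the first exposure was tested as a difference of responses, C28PLT minus C35P. XTH22 had a log2 difference of 4.67 at 2 h (SE 1.2, edgeR adjusted p = 1), and ERF104, ERF6 and OXI1 had 3.32 (SE 0.847), 3.14 (SE 1.11) and 3.10 (SE 1.07), each with an edgeR adjusted p of 1. CBF3 differed by 0.24 (SE 1.06) and COR15A by -0.23 (SE 0.655). At 24 h XTH22, which fell in the control but was not called in C28PLT, differed by 5.12 (SE 1.22, edgeR adjusted p = 0.816), and OXI1 by 2.99 (SE 1.05, edgeR adjusted p = 0.967). In total edgeR called 0 genes at each of 2, 4, 6, 12 and 24 h. At an unadjusted p under 0.05 there were 306, 436, 322, 289 and 623, and DESeq2 called 0, 7, 0, 0 and 1. Without the C35P 0 h library of Exp3 edgeR called 5, 39 and 7 genes at 2, 4 and 24 h.

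Early cold-induced factors differed as a list in their change from 0 to 2 h (median difference 1.68, camera adjusted p = 1.72e-15, and adjusted p = 0.0422 with an estimated correlation, or 0.0604 with that and the length and GC offset), with 5 called adjusted over the list alone. At 4, 6, 12 and 24 h the medians were 1.80, 1.51, 1.57 and 1.51 (camera adjusted p from 8.2e-13 to 2.86e-07, and adjusted p = 0.0587, 0.0999, 0.152 and 0.231 with an estimated correlation). The 24 h call was lost without Exp2 (0.0522). Redox genes differed by a median of 0.21 at 2 h and 0.26 at 6 h (camera adjusted p = 0.00571 and 0.002, and adjusted p = 0.0422 and 0.0333 with an estimated correlation, or 0.0604 and 0.0808 with that and the length and GC offset), and both were lost without Exp3 (0.113 and 0.063). Touch genes differed by 1.82 at 2 h and 1.92 at 4 h (camera adjusted p = 3.47e-06 and 6.26e-08, and adjusted p = 0.0696 and 0.0587 with an estimated correlation). Jasmonate genes differed by 1.56 at 24 h (camera adjusted p = 3.67e-06, and adjusted p = 0.509 with an estimated correlation). For CBF/DREB1 factors the difference at 2 h was 1.83 (camera adjusted p = 0.0487, and adjusted p = 0.61 with an estimated correlation), lost without Exp2 (0.105) or Exp3 (0.339). Salicylate (0.78, camera adjusted p = 2.93e-05), heat-shock (-0.75, 0.0449) and ribosome genes (-0.25, 0.0449) at 2 h each had an adjusted p of 0.61 with an estimated correlation. The first was lost without Exp2 (0.052), the second without Exp3 (0.339) and the third without Exp2 or Exp3 (0.152 and 0.184). All these differences use the same 6 libraries at 0 h. The mean of the early factors, C28PLT minus C35P, was -1.06 at 0 h against 0.439 at 2 h (1.14, -0.298 and 0.481 in Exp1, Exp2 and Exp3). That of the touch genes was -1.4 at 0 h against 0.221 at 2 h, and that of the redox genes -0.441 (-0.395, -0.582 and -0.347) against 0.0348 at 2 h and 0.0777 at 6 h. In the means over the experiments, most of the difference of responses in these 3 lists therefore lies at 0 h. This does not hold in each experiment. The early factors stood at -0.77, -2.32 and -0.073 at 0 h in Exp1, Exp2 and Exp3, so in Exp1 and Exp3 more of their difference lies at 2 h. For the touch genes Exp3 had 0.0773 at 0 h and 0.556 at 2 h.

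The size of the response was compared on genes called in C28P libraries, which neither group shares. The dispersion behind these calls was, however, estimated over all 54 libraries, so the choice of genes is not fully independent of both groups. The sets were called with the 0 h library of Exp1 that stands apart and were not redrawn without it. At 2 h, 38 genes rose with that library and 404 without it. At 24 h the 2032 genes that rose in C28P went up by a mean of 1.53 ± 0.127 log2 units in C28PLT and by 1.68 ± 0.431 in C35P (SD, n = 3), a difference of -0.15 (two-sided exact permutation test, p = 0.9). For fallen genes the sign of the change was turned, so a negative difference means a smaller fall in C28PLT. The 2290 fallen genes fell by a mean of 1.29 in C28PLT and 1.57 in C35P, a difference of -0.28 (exact p = 0.5). Both differences rest on Exp1, in which C35P had 2.17 for risen genes against 1.39 and 1.47 in Exp2 and Exp3. Without Exp1 the differences turned to 0.125 for risen and 0.123 for fallen genes. At 2 h the differences were -0.055 over 37 risen genes (exact p = 0.6) and -0.29 over 40 fallen genes (exact p = 0.3). At 4, 6 and 12 h they were 0.0069, -0.043 and -0.037 for risen genes (exact p = 0.9, 1 and 0.5) and -0.15, -0.11 and -0.21 for fallen ones (exact p = 0.7, 0.8 and 0.7). This test of 3 values against 3 does not pair the experiments, and its smallest p is 0.1. C28PLT stood below C35P in all 3 experiments for the fallen genes at 2 h (1.85, 1.52 and 1.39 against 2.02, 1.77 and 1.85) and for the risen genes at 12 h (2.13, 1.78 and 1.73 against 2.15, 1.79 and 1.81).

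Age alone is addressed by C35P against C28P. At 0 h the clock output gene FKF1 was 38.1-fold lower in C35P (log2 -5.25, SE 0.891, edgeR adjusted p = 0.0112, n = 3), the light-signalling factor LZF1 (AT1G78600) 8.18-fold lower (SE 0.565, edgeR adjusted p = 0.0237) and PRR5 21.9-fold lower (edgeR adjusted p = 0.0371). AT1G17665 was 12.3-fold and AT1G56300 16.7-fold lower, and these last 2 were named after their values were seen. The 5 calls rest on the C28P library of Exp1, in which FKF1 stood at 37.9 CPM against 0.644 and 0.619. Without it 0 genes were called, and FKF1, LZF1 and PRR5 differed by -0.89, -0.28 and 0.21 (edgeR adjusted p of 1). Without any 1 of the C35P libraries 0 genes were called as well, and without the C28P libraries of Exp2 or Exp3 73 or 55 were. With the length and GC offset PRR5 was no longer called. At 2, 4, 6, 12 and 24 h edgeR called 0 genes, with 326, 251, 528, 220 and 339 at an unadjusted p under 0.05, and DESeq2 called 1, 0, 0, 0 and 0 (51 at 0 h). The differences of responses between C35P and C28P gave 0 calls at each time with edgeR, with 289, 262, 309, 315 and 417 at an unadjusted p under 0.05, and 2, 1, 2, 10 and 5 with DESeq2. Without the C28P 0 h library of Exp2 edgeR called 3, 6, 8, 10 and 7 genes, and without that of Exp3 4, 6, 7, 8 and 8.

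By list at 0 h, COR and LEA genes (median -0.63, camera adjusted p = 0.000146), flavonoid genes (-0.35, 0.000227) and ribosome genes (-0.31, 2.65e-05) were lower in C35P than in C28P. With an estimated correlation their adjusted p was 0.608, 0.608 and 0.42. Clock genes were called down by camera (adjusted p = 0.00604, and adjusted p = 0.608 with an estimated correlation) with a mean of -0.91 and a median of 0.071. Without the C28P library of Exp1 these lists had adjusted p of 0.749 (COR and LEA), 0.18 (flavonoid), 0.581 (ribosome) and 0.749 (clock). At 2, 4, 6, 12 and 24 h camera called 6, 4, 5, 7 and 4 lists between C35P and C28P, and 0 of these with an estimated correlation.

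The state after priming and lag was set against the state before it, C28PLT against C28P at 0 h, which holds age as well. PHI-1, a growth-related gene, was 52.7-fold lower in C28PLT (edgeR adjusted p = 0.0348), PRR5 42.8-fold lower (edgeR adjusted p = 0.0087) and the cell-wall genes XTH22 and XTR6 were 21.3-fold and 14.6-fold lower (edgeR adjusted p = 0.0352 and 0.0179). All 26 called genes were lower. Without the C28P library of Exp1 0 genes were called, without those of Exp2 and Exp3 58 and 118, and without the C28PLT libraries of Exp1, Exp2 and Exp3 0, 14 and 0. Without the first of these PRR5 stood at -0.76 (edgeR adjusted p = 0.881), and the call of XTH22 was lost without any of 5 of the 6 libraries (edgeR adjusted p of at most 0.376). At an unadjusted p under 0.05 there were 1510 genes, and DESeq2 called 129. The differences of responses between C28PLT and C28P gave 0 calls at each time with edgeR, with 650, 928, 817, 881 and 1461 at an unadjusted p under 0.05, and 10, 37, 13, 25 and 40 with DESeq2. Without the C28P 0 h library of Exp2 edgeR called 4, 4, 6, 23 and 33 genes, and without that of Exp3 4, 19, 5, 19 and 16. By list, the early cold-induced factors (median -1.37, camera adjusted p = 1.49e-08), touch genes (-1.07, 0.00155) and senescence genes (1.05, 0.00594) had an adjusted p of 0.301 with an estimated correlation. The second of these was lost without Exp2 (0.191). In total camera called 9 lists there, and 0 with an estimated correlation.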

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

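In this part, the tests of the material mixed into 1 library and of its harvest time, those of the deviating sets and that of the offset on touch genes were chosen only after the result was seen.

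A difference between groups in the tested response singled out the early cold-induced transcription factors at 2 h, with a median of 1.68 for C28PLT minus C35P (camera adjusted p = 0.0422 with an estimated correlation, or 0.0604 with that and the length and GC offset) and 2.06 for C28PLT minus C28P (0.0116). Redox genes were singled out in the same way, with 0.211 at 2 h (0.0422, or 0.0604 with the offset) and 0.261 at 6 h (0.0333, or 0.0808 with the offset) for C28PLT minus C35P, and 0.343 at 2 h for C28PLT minus C28P (0.0091). In 7 cases, of 330 looked at (22 lists at 5 times in 3 pairs of conditions), the means of all 3 experiments moved one way in C28PLT and the other way in C28P. If every sign were a coin flip, 3.125% of cases would be opposite in this way. Signs are not coin flips here, as many lists change the same way in each condition. This rate therefore cannot tell whether 7 of 330 is many or few. All 7 lie in this 1 pair and share its 0 h libraries, and lists and times are not independent, so no p is given. These 0 h libraries include that of C28P in Exp1, which stands apart. One of them, redox genes at 2 h, is also among the tested differences. By that rule the difference itself was not tested. These are the early factors at 24 h (1.8), redox genes at 2 h (0.752), 4 h (0.505) and 24 h (0.63), touch genes at 6 h (2.1), jasmonate genes at 12 h (1.18) and reference genes at 4 h (0.244). The matching list tests by limma's camera gave, in that order, adjusted p = 0.18, 0.0091, 0.297, 0.18, 0.104, 0.501 and 0.487 with an estimated correlation. Much of these contrasts lies at 0 h, where C28PLT minus C28P was -0.477 for redox genes (0.275, 0.0272 and 0.153 at 2, 4 and 24 h) and -1.18 for the early factors (0.621 at 24 h). At 24 h the early factors went up by 0.744 ± 0.779 in C28PLT and down, with a value of -1.06 ± 0.706, in C28P (SD, n = 3).

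The C28P library of Exp1 at 0 h holds clock transcripts and CBF3 far above the other experiments (CBF3 at 71.6 CPM against 1.02 and 4.14), while CBF2 stood at 36.5 against 6.98 and 36.1. An exchange of labels with another C28P library of Exp1 is argued against, since 0 of those others sat closest to a time that was not their own. The library itself sat closest to 2 h (correlation 0.515, against 0.469 for 0 h). Of 54 libraries, 2 sat closest to a time that was not their own. The other was the C35P 4 h library of Exp1, closest to 6 h (0.547, against 0.468 for 4 h). Cold-treated material mixed in would bring clock and cold-induced genes at 1 share. For material of 4 h the values go against this, as the median shares of the 4 h change were 0.406 over 8 clock and 0.194 over 14 COR and LEA genes (permutation p = 0.00138). That test permutes genes within 1 library. Genes regulated together are not independent, so its p says nothing of the spread between libraries. Shares of the 2 h change, taken from each of the 9 libraries at 2 h, had medians of at least 0.866 over 3 clock and at most 0.685 over 8 cold-induced genes. Against the mean, FKF1 had 2.05, CBF1 0.0358 and CBF2 0.0246. An exact test of these sets, which also permutes genes of 1 library, gave p = 0.103. The median share over 219 genes risen at 2 h was 0.628 (quartiles 0.358 and 1.07). Material of 2 h is thus left undecided, and later or mixed times were not tried. A harvest later in the warm day fits the share of 0.194, which lies barely below 0.5 times 0.406. No biological explanation was tested for this library.

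Libraries of the same condition and experiment deviate together from their group means. A bias with transcript length and GC as the whole cause is argued against, as 43.7% of the within-group variance lay between the 9 sets after that offset, where the highest of 100 random groupings gave 23.2%. For inflorescence tissue, a jasmonate response that differs between sets and plants further on towards flowering, Spearman's rho over the 9 sets between the leading component and the list means was 0.717, 0.817 and 0.45 (permutation p = 0.0376, 0.0113 and 0.229). These cannot be told apart, since they were drawn from the leading genes of that same component (such as AP1 and PDF1.2A), and salicylate (0.867) and senescence genes (0.9) rank with it at least as closely. Age and priming are the same within a condition, so their mean effects go out with its group means and cannot set these deviations. An effect of either that differs in size between experiments is not removed in this way and was not tested.

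Touch genes were lower in C28PLT than in C35P at 0 h. A bias with transcript length and GC is argued against, as the median was -1.23 with the offset and -1.41 without. A short-lived response of the control plants at harvest, such as to handling, fits the median of -1.3 of the early cold-induced factors, which such stimuli also induce, and it could then also set part of the differences of responses, as these use the same libraries. Whether 1 experiment sets the difference cannot be told apart, since the medians were -1.37, -2.08 and 0.0786 and Exp3 alone stood above 0. An effect of priming itself, which the design names, could lower both lists as well, so this fit does not favour handling over it. Both lists were also lower in C28PLT than in C28P at 0 h. Priming, and the older age in days of C28PLT plants, stay open and untested.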

How the results depend on the processing

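The tests without the C28P 0 h library of Exp1, with the length and GC offset, with blocks for sets and of each gene with 1 library left out were chosen after the result was seen. With 3 libraries per group, simulated 2-fold changes were often missed, and depth limits only genes near the filter. The list calls followed here are those against 0 h, between conditions at 0 h, between C28PLT and C35P later, and in C28PLT minus C35P, and the gene calls those at 2 and 24 h against 0 h and between conditions at 0 h. With the offset, 165 of 192 list calls held, with RLE factors 186, with the replicate block 188, and without replicate 1, 2 or 3 147, 155 and 142. With an estimated correlation 7 of them held (C28PLT minus C28P, not among them, had another 2 at 2 h). Of 483 gene calls, DESeq2 kept 482, RLE factors 475, the replicate block 479 and the offset 469, and 2367 of 2898 calls held with 1 library left out. The paired fit with the replicate block ended the calls of XTR6 at 0 h, ERD4 in C28P, TT8 in C35P and LOX6 in C28PLT at 24 h, and in C28P those of the regulators of CBF at 2 h (camera adjusted p = 0.0503), photoprotection at 4 and 12 h (0.0537 and 0.0588) and membrane lipid genes at 6 h (0.057), and it changed no other call of these genes and lists. In all settings 307 of the 483 gene calls and 5 of the 192 list calls held. For the changes below, the cause was not tested.

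With the replicate block C28P at 2 h had 155 genes and C28PLT against C35P at 0 h 0. Without the low-count filter the 0 h comparisons had 0 (C28PLT against C35P), 2 (C35P against C28P) and 14 (C28PLT against C28P), and with the offset 7, 9 and 45, with C28P at 2 h at 141 and C28PLT minus C28P at 12 h at 1. With offset and replicate block C28P had 270 at 2 h and 2827 at 4 h, C35P 742 and 3363, C28PLT 967 at 2 h, C28PLT against C35P at 0 h 2, C28PLT against C28P at 0 h 57, and C28PLT minus C28P 2 at 12 h and 2 at 24 h. With a block per set C28P had 398 and 2906 at 2 and 4 h, C35P 839 and 3311, C28PLT 1206 and 4080, and C28PLT minus C28P 1 at 4 h. With that and the offset, C28P had 606, 4042, 6447, 7673 and 9078 from 2 to 24 h, C35P 1145, 4544, 6464, 8469 and 8997, C28PLT 1570, 4962, 6520, 8653 and 8882, and C28PLT minus C28P 3 at 12 h and 12 at 24 h. With only the groups compared, C28P had 0, 272, 1360 and 1960 from 2 to 12 h, C35P 211 at 2 h and 2793 at 24 h, C28PLT 2823 at 24 h, the 0 h comparisons 0, 0 and 8, and C28PLT minus C28P 4 at 2 h. DESeq2 called 238 (C28P at 2 h), 48, 51 and 129 (0 h comparisons), 1 (C35P against C28P at 2 h), 7 and 1 (C28PLT minus C35P at 4 and 24 h), 10, 37, 13, 25 and 40 (C28PLT minus C28P) and 2, 1, 2, 10 and 5 (C35P minus C28P).

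Leaving out 1 library gave 19 to 631, 662 to 2377, 1943 to 5347, 2912 to 5096 and 4125 to 6961 genes in C28P, 194 to 316, 1398 to 2182, 2646 to 3578, 3931 to 4860 and 4084 to 6043 in C35P, and 299 to 570, 1719 to 2948, 2780 to 3280, 3791 to 5061 and 4054 to 4797 in C28PLT. The 0 h comparisons gave 0 to 93, 0 to 73 and 0 to 118, and C28PLT against C35P at 6 h 0 to 1. The differences of responses ran from 0 to 5, 39, 0, 0 and 7 (C28PLT minus C35P), 4, 19, 6, 23 and 33 (C28PLT minus C28P) and 4, 6, 8, 10 and 8 (C35P minus C28P).

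The size of the response on genes risen at 4 h changed sign with the median over genes (-0.00324), RLE factors (-0.0332) and the offset (-0.0528). With an experiment left out it also changed sign for risen genes at 2 h (-0.127 to 0.0244), 4 h (-0.0171 to 0.0344), 6 h (-0.139 to 0.00596, and 0.00481) and 24 h (-0.366 to 0.125), and for fallen genes at 6 h (-0.247 to 0.0445) and 24 h (-0.548 to 0.123). Camera turned in direction with an experiment left out, with adjusted p from lowest to highest, in C28PLT against C35P for light harvesting (0.00269 to 0.481) and jasmonate at 0 h (8.06e-07 to 0.66), floral organ markers at 2 h (0.00894 to 0.825), and COR and LEA (0.0162 to 0.985), flavonoid (9.96e-05 to 0.516) and salicylate genes at 6 h (4.47e-07 to 0.353). It also did in C35P against C28P at 0 h for COR and LEA (2.41e-07 to 0.0891) and clock genes (7.85e-05 to 0.0569, and 0.749 without the C28P library of Exp1), and in C28PLT against C28P for ribosome genes (0.0129 to 0.583, and 0.929 without that library). PRR5 in C35P against C28P at 0 h ran from -5.02 to 0.211.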

Other observations

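In this part the only test beyond the planned ones is that of CBF3 without the C28P 0 h library of Exp1, which was added after the result was seen. The named examples of the middle times were also chosen after their values were seen.

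At the times between 2 and 24 h, CBF3 rose 9.62-fold, 90.9-fold and 121-fold at 4 h in C28P, C35P and C28PLT (SE 0.793, 0.931 and 0.947, n = 3), and 13.3-fold in C35P and 12.9-fold in C28PLT at 12 h, where C28P had a fold of 1.39 (edgeR adjusted p = 0.713). The C28P values rest on the 0 h library of Exp1, and without it CBF3 rose 97-fold at 4 h and 14-fold at 12 h (edgeR adjusted p = 4.63e-07 and 0.000194). COR15A rose 3.94-fold, 7.21-fold and 5.25-fold at 4 h and 20.1-fold, 29.7-fold and 22.5-fold at 12 h. TT4, of flavonoid synthesis, had an edgeR adjusted p of 0.658, 0.726 and 0.683 at 4 h and rose 4.49-fold, 3.72-fold and 3.68-fold at 12 h. HSFA2 fell 14.3-fold, 18.9-fold and 62.9-fold at 4 h. COR and LEA genes rose in 13, 14 and 14 of 19 cases at 4 h (camera adjusted p of at most 8.15e-13, and adjusted p = 0.217, 0.117 and 0.18 with an estimated correlation). Light harvesting genes fell in 10, 12 and 12 of 21 cases at 12 h (14 adjusted over the list alone in each; camera adjusted p of at most 5.57e-07, and adjusted p = 0.257, 0.327 and 0.346 with an estimated correlation). At 12 h flavonoid genes were lower in C35P than in C28P (median -0.55, camera adjusted p = 7.64e-10, and adjusted p = 0.543 with an estimated correlation). The 7 root hair markers, of a tissue outside the rosette, reached at most 6 counts or 0.201 CPM in any library.

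Other splits of the 6 or 12 libraries of each comparison, 10 for each, are too few for a share under 0.05. For a time against 0 h, each split regrouped the libraries of all 3 conditions at once. Changes with time then lie within groups and raise the shared spread, so low counts in the other splits are partly built in. As many genes as the real groups were called in 2 of 10 splits for C28P at 2 h (highest of the others 563) and in 1 of 10, the real one, for C28P at 4, 6, 12 and 24 h (highest of the others 0, 203, 0 and 0). For C35P it was 1 of 10 at each time (0, 1, 0, 0 and 1 from 2 to 24 h) and for C28PLT as well (0 at each time). Between conditions at 0 h it was 4 of 10 for C28PLT against C35P (highest 48), 8 for C35P against C28P (262) and 5 for C28PLT against C28P (92). Where 0 genes were called in the real groups, any split gives as many, so 10 of 10 is fixed and says nothing there, and only the highest counts are informative. From 2 to 24 h these were 10, 0, 15, 0 and 787 for C28PLT against C35P and 111, 632, 542, 786 and 1544 for C35P against C28P, and 0 at each time among the splits that part all pairs of an experiment, as the groups do. At 0 h the highest of the splits that part all pairs were 9, 79 and 74 in the order above. For the differences of responses the highest counts were 1, 0, 0, 0 and 1 for C28PLT minus C35P, 6, 5, 4, 11 and 0 for C28PLT minus C28P, and 0, 0, 0, 0 and 3 for C35P minus C28P.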
